A study of Mus musculus with 10 samples.

How the data were processed

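RNA of flow-sorted lung neutrophils was measured in 10 libraries, 2 from uninfected wild-type, 2 from uninfected Mrgpra1 knockout, 3 from infected wild-type and 3 from infected Mrgpra1 knockout mice. Per the labels' protocols, RNA was isolated on Qiagen RNeasy columns with a DNase step, made into cDNA with an ultra-low-input SMART-Seq kit from 1 ng, and turned into libraries with Nextera XT. Such libraries carry no mark of the strand, so reads of overlapping genes on opposite strands cannot be told apart. The submitters' processing notes name fastp, Salmon and DESeq2, without versions or roles, and the mouse genome build mm10. The deposited values are TPM per gene as the authors computed them, and each library sums to the same total over the genes listed. The annotation release and the way transcripts were summed to genes are not given in the sources used here. TPM keeps no read depth, so the depth per library is unknown, no counting interval or floor was computed, and no count test was run. A gene at 0 is described only as listed at 0, and no fold change is given against a group that is at 0 throughout, nor an interaction in which any group is.

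The table listed 34866 genes with Ensembl identifiers and symbols, of which 11331 were at 0 in every library. Of the identifiers, 32574 matched the reference annotation with their version and 34582 without it, and 26 entries repeated a symbol held by another identifier. Columns were assigned to samples by genotype, condition and replicate number; columns marked naive were read as PBS and those marked treated as S. pneumoniae, the only conditions in the labels. No column was left unused.

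Values were transformed to log2(TPM + 1), and genes at 1 TPM or more in at least 2 libraries were tested, 12367 in all. Fold changes are on this scale, which understates the change of genes with low TPM. limma 3.58.1 in R 4.3.3 fitted the 4 group means to all 10 libraries at once with empirical Bayes moderation and a variance trend on expression, with 6 residual degrees of freedom, because the uninfected groups had only 2 libraries each. The contrasts were infection within each genotype, genotype within each infection state, their interaction, and the averages of infection over genotypes and of genotype over infection. All tests were two-sided, and genes were called at a Benjamini-Hochberg adjusted p under 0.05 within a contrast. The averages of 1 factor over the other use the mean of both within-group contrasts.

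The 36 lists of neutrophil states, functions and cell type markers were written from general knowledge. Lists with at least 3 tested members were tested against all other genes with camera, at a preset correlation of 0.01 between genes and again with the correlation estimated from the data. Its p-values were adjusted over the 245 tests of a list in a contrast. With an estimated correlation, only the interferon-stimulated genes were called among the lists reported, in each contrast except genotype without infection. Genes counted as adjusted over the list alone had a Benjamini-Hochberg adjusted p under 0.05 among the list members only. Correlations of log2 fold changes were taken across genes, which are not independent replicates.

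Named genes followed a rule. In each contrast these were the 12 called genes with the largest positive and the 12 with the largest negative log2 fold change that had a mean of at least 10 TPM in the higher group and no overlap between the libraries of the groups. Unnamed loci, pseudogenes, and symbols beginning with Gm or ending in Rik were left out. For each list at most 4 members with the smallest p were added, and any member of the N1-type and N2-type lists. Where under 6 genes passed in a contrast, the 6 with the smallest p were added as not past the threshold. The text names a subset in the order of this rule, with the other members of the receptor family as an addition. The groups, the tests, the lists, this rule and the alternatives were fixed before the data were examined, except 1 alternative and the tests named as later choices in the closing section.

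The alternatives were a pseudocount of 0.1 or 5 TPM, no filter or a filter of 5 TPM, median-of-ratios scaling, quantile normalization, no variance trend, sample weights, the replicate number as a block, a fit of only the 2 groups compared, a minimum log2 fold change of 1 in size, and each library left out in turn. The removal of a trend on exon length from each library was added after the data were seen. The procedure was tested on simulated data with 200 changed genes per contrast. The changed genes had a mean level of about 10 TPM or more, and noise was drawn independently for each gene. Recovery at lower levels was not simulated. For infection in wild type it recovered 33% of 2-fold and 89% of 4-fold changes among 11829 genes, and for infection in the knockout 21% and 85% among 11831. For genotype it recovered 15% and 73% without infection and 34% and 87% with infection, each among 11819 genes. For the interaction it recovered only 3% and 36% among 11824 genes, so most true differences of that size would be missed there. For the averages over the other factor it recovered 62% and 95% for infection among 11784 genes, and 58% and 98% for genotype among 11817. Of the genes called in the simulations, 7 of 129, 6 of 112, 7 of 95, 4 of 125, 1 of 40, 14 of 171 and 5 of 161 were unchanged ones, in the order just given. A list with raised members was called by camera in 7 of 7 simulated contrasts and an unchanged list in 0. The simulated genes were uncorrelated, so this does not test the list calls under the correlations in the data. Those were estimated at 0.224 for the NF-kB list and 0.608 for the secondary and tertiary granule list. The identity of the Mrgpra1 transcript was compared with all other annotated transcripts by 31-base words in the reference annotation. Tables and plots were made with Python 3.11.15, pandas 2.3.3 and matplotlib 3.10.9.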

Results

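Neutrophils were sorted by flow cytometry from mouse lungs as viable, DAPI-negative cells that carried CD11b and Ly6G on their surface, and their RNA was sequenced in 10 libraries. The mice were wild type (Mrgpra1+/+) or knockout (Mrgpra1-/-) for Mrgpra1, which encodes a G protein-coupled receptor of the Mas-related family. They had received either PBS, a buffered salt solution, or Streptococcus pneumoniae strain 6303, a Gram-positive bacterium that causes pneumonia. There were 2 libraries from uninfected wild-type mice, 2 from uninfected knockout mice, 3 from infected wild-type mice and 3 from infected knockout mice. The title of the series links Mrgpra1 to neutrophil activation and to the balance of N1 and N2 states, names used for pro-inflammatory and for tissue-repair or tumor-promoting neutrophils. Expression was given as TPM, a unit that scales each library to the same total and corrects for transcript length. It keeps no read depth, so the depth of each library is unknown. Between 9818 and 10764 genes per library were listed at 1 TPM or more, and the 10 most abundant genes took 22.2% to 31.4% of the TPM. The labels used here name no animal, cage or batch for a library, so the p-values measure only the spread between libraries, and infection and an unrecorded batch cannot be told apart.

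The targeted gene was examined first. Mrgpra1 (ENSMUSG00000050650.7) lies on the minus strand of chromosome 7 from position 47334875 to 47354240 in mm10. It was listed at 0 in every library except the second uninfected knockout library, where it stood at 0.0209 TPM. It was therefore below the expression filter, no difference between genotypes was computed, and its level does not check the genotype labels in either direction. Among the other protein-coding members of the family, only Mrgpra2a and Mrgpra2b, neighbors of Mrgpra1 on chromosome 7, passed the filter; the pseudogene Mrgprc2-ps also passed, at 2.25 to 5.69 TPM, and was called in no contrast. Mrgpra2a stood at 16.4 ± 2.73 TPM in uninfected wild-type and 38.5 ± 4.31 TPM in infected wild-type neutrophils, and at 15.7 ± 5.27 and 43.9 ± 10.2 TPM in the knockout (mean ± SD). With infection it rose by 1.19 ± 0.27 on the log2 scale (± SE) in wild type (adjusted p = 0.0366) and by 1.44 ± 0.27 in the knockout (adjusted p = 0.00733). Mrgpra2b rose by 1.18 ± 0.27 in wild type (adjusted p = 0.0358), and its difference in the knockout, 0.71 ± 0.27, was not past the threshold (adjusted p = 0.109). The wild-type calls were lost in 6 cases of 1 library left out for Mrgpra2a (adjusted p up to 0.201) and in 5 for Mrgpra2b (up to 0.224), both highest without the first uninfected wild-type library. The knockout call of Mrgpra2a was lost without the first uninfected knockout library (adjusted p = 0.0644). Neither gene was called between genotypes, with adjusted p of 0.922 and 0.356 without infection and 0.805 and 0.783 with infection. Mrgpra2a and Mrgpra2b are close paralogs, so the division of reads between them is uncertain.

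Infection separated the libraries more than genotype did. The first principal component of log2(TPM + 1) held 29.6% of the variance and placed the 4 uninfected libraries at -58.7 to -24.4, the infected wild-type libraries at 16.8 to 19.4 and the infected knockout libraries at 29.9 to 51.1. The second component, with 16.8% of the variance, set apart the first uninfected wild-type library at 77.5, with all others between -29.3 and 22.1. Correlations between libraries of 1 group, computed across genes, were 0.922 to 0.953. Some between groups were as high. The third infected knockout library reached 0.955, 0.945 and 0.943 with the infected wild-type libraries, against 0.942 and 0.937 with its own group. The second uninfected wild-type library reached 0.947 with the second uninfected knockout library, against 0.922 with its own group.

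**Figure D1:**
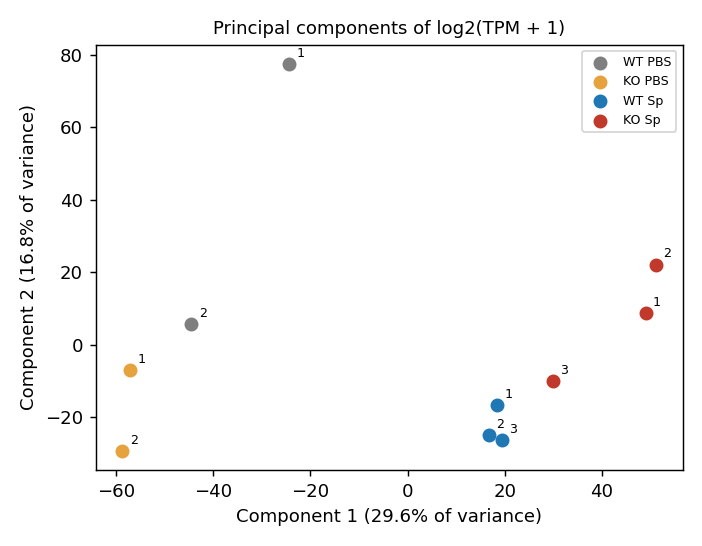
Principal components of log2(TPM + 1) for the 10 libraries, 1 point per library numbered by replicate, colored by genotype (WT, wild type; KO, knockout) and treatment (PBS; Sp, S. pneumoniae). Uninfected libraries lie at -58.7 to -24.4 and infected ones at 16.8 to 51.1 on the first axis, and the first uninfected wild-type library lies alone at 77.5 on the second axis.

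In wild-type neutrophils, infection was followed by higher transcript levels of inflammatory cytokines and chemokines. Il1a, which encodes a cytokine of the interleukin 1 family, went from 4.31 ± 3.57 to 317 ± 21.4 TPM (mean ± SD, n = 2 and 3) and rose by 6.09 ± 0.36 (log2 fold change ± SE, adjusted p = 1.89e-05). The chemokine genes Ccl4 and Ccl3 rose by 5.56 ± 0.12 and 4.09 ± 0.12, and Ccl4 reached 12452 ± 1077 TPM from 263 ± 5.34 TPM. Cxcl10, an interferon-induced chemokine that attracts T cells, rose by 4.19 ± 0.19, from 17.8 ± 0.433 to 343 ± 35.6 TPM. Csf3, the gene of granulocyte colony-stimulating factor, rose by 4.76 ± 0.27, and Cish, a feedback inhibitor of cytokine signaling, by 4.55 ± 0.38. Ifi47, an interferon-inducible GTPase, rose by 4.77 ± 0.35, Mreg (melanoregulin) by 4.94 ± 0.30, Slc31a2, a copper transporter gene, by 4.72 ± 0.31, Rab15 by 4.69 ± 0.32 and Ralgds, an exchange factor for Ral GTPases, by 4.33 ± 0.36. Hmga1b, a copy of an architectural chromatin protein gene whose reads are uncertain, rose by 4.59 ± 0.98 (adjusted p = 0.0263). Of 12367 genes tested with limma, 682 were called, 400 higher and 282 lower.

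The transcripts with the largest falls in infected wild-type neutrophils are known mostly from other cells. Hemoglobin genes fell, with log2 fold changes of -3.89 ± 0.41 for Hbb-bt, -3.81 ± 0.33 for Hbb-bs, -3.61 ± 0.32 for Hba-a2 and -3.53 ± 0.34 for Hba-a1, near-identical copies whose separate values are uncertain. Airway and alveolar epithelial genes fell as well, with log2 fold changes of -4.00 ± 0.77 for Cbr2, -3.86 ± 0.40 for the club cell secretoglobin Scgb1a1, -3.40 ± 0.72 for Scgb3a2 and -2.97 ± 0.55 for the surfactant gene Sftpc. Rrp1b, a nucleolar protein gene, changed by -3.83 ± 0.40, the nuclear receptor gene Nr4a2 by -3.47 ± 0.77, Fabp1, a fatty acid binding protein gene, by -3.21 ± 0.53 and Retnla, a gene of alternatively activated macrophages, by -2.83 ± 0.36 (adjusted p = 0.00172). Summed TPM of the erythroid markers was 7970.4 ± 786.7 (SD) in uninfected and 632 ± 178.8 in infected wild-type libraries, and that of the lung epithelial markers was 1866.3 ± 641.4 and 227.3 ± 22.2.

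Targets of the transcription factor NF-kB rose as a group, with 19 of 29 called higher and 0 lower (21 and 0 adjusted over the list alone). Their median log2 fold change was 1.41 (camera adjusted p = 2.3e-25, and adjusted p = 0.0969 with an estimated correlation). Among them Sod2, the mitochondrial superoxide dismutase, rose by 3.30 ± 0.21 and Icam1, an adhesion molecule gene, by 2.53 ± 0.17. Of 19 cytokine and cytokine inhibitor genes, 8 rose and 1 fell (11 and 2 adjusted over the list alone), among them Il1rn, the interleukin 1 receptor antagonist, by 3.72 ± 0.19. For the cytokine list, camera gave adjusted p = 3.36e-09, and adjusted p = 0.285 with an estimated correlation. Chemokine genes rose in 7 of 15 cases and fell in 0 (9 and 0 adjusted over the list alone). Their camera test gave adjusted p = 2.29e-12, and adjusted p = 0.0969 with an estimated correlation. Of 47 interferon-stimulated genes, 20 rose and 0 fell (25 and 0 adjusted over the list alone). They had a median of 0.80 (camera adjusted p = 3.41e-18, and adjusted p = 0.0128 with an estimated correlation). Irgm1, an immunity-related GTPase gene, rose by 3.35 ± 0.23, Gbp2, a guanylate-binding protein gene, by 2.36 ± 0.18, and Cd274, which encodes the checkpoint ligand PD-L1, by 3.12 ± 0.20.

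Genes of survival and pathogen sensing also changed in wild type. 10 of 27 apoptosis and survival genes rose and 0 fell (10 and 1 adjusted over the list alone). For apoptosis and survival, camera gave adjusted p = 3.23e-07, and adjusted p = 0.135 with an estimated correlation. They included the pro-survival Bcl2a1a at 3.41 ± 0.16, Bcl2a1b at 2.10 ± 0.12 and Bcl2a1d at 1.82 ± 0.14, paralogs with uncertain separate values, and Cflar, an inhibitor of caspase 8 activation, at 1.99 ± 0.20. Pattern recognition and phagocytic receptor genes rose in 6 of 30 cases and fell in 0 (9 and 1 adjusted over the list alone), with the C-type lectin genes Clec4n at 2.36 ± 0.14, Clec5a at 1.41 ± 0.22 and Clec4e at 0.74 ± 0.12 and the inhibitory Fc receptor gene Fcgr2b at 2.09 ± 0.29. The receptor list had camera adjusted p = 0.000296, and adjusted p = 0.56 with an estimated correlation. Transcripts of secondary and tertiary granules went both ways, 2 higher and 2 lower of 22 (3 and 6 adjusted over the list alone). The granule list had camera adjusted p = 0.706, and adjusted p = 0.976 with an estimated correlation. Lcn2, which encodes an iron-sequestering lipocalin, rose by 1.44 ± 0.16 and Chil1 by 1.09 ± 0.23, while Camp, the cathelicidin gene, changed by -1.08 ± 0.15 and the protease gene Adam8 by -1.43 ± 0.32. The class II antigen presentation genes H2-Aa, H2-Eb1 and H2-Ab1 changed by -1.76 ± 0.27, -1.89 ± 0.33 and -1.59 ± 0.30. Of 6 dendritic cell markers 0 were called higher and 2 lower (0 and 2 adjusted over the list alone), and the lower ones were H2-Aa and H2-Ab1 themselves. For these markers camera gave adjusted p = 0.0163, and adjusted p = 0.622 with an estimated correlation, and the call was lost without the second uninfected wild-type library (adjusted p = 0.119). Whether other cells in the sort account for the class II values is left open.

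For each of the 682 genes called in wild type, the libraries of both groups did not overlap, which chance alone gives in 20% of unselected genes. The call on the same libraries favors such separation, so it adds no independent support. The median of all genes stood at -0.18, and with median-of-ratios scaling at -0.10, where the calls were 489 higher and 191 lower. Quantile normalization gave 497 and 210, and removal of the length trend 554 and 164. The number called was 298 without the first uninfected wild-type library, 382, 352 and 358 without the first, the second and the third infected wild-type library, and 393 when only these groups were fitted. Of 56 genes named for this comparison and called, 43 were called without each library in turn, and the others were Hmga1b, Cbr2, Nr4a2, Scgb3a2, Fabp1, Sftpc, Chil1, Adam8, Arg1, Slc16a3, H2-Ab1, Mrgpra2a and Mrgpra2b.

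In knockout neutrophils, interferon-induced transcripts were among those that rose most with infection, beside cytokine, chemokine and other genes. Cxcl10 went from 18.6 ± 3.85 to 2074 ± 319.5 TPM (mean ± SD, n = 2 and 3), a rise of 6.72 ± 0.19 (log2 fold change ± SE, adjusted p = 8.7e-08), and the related chemokine gene Cxcl9 rose by 6.66 ± 0.29 to 109 ± 6.93 TPM. Nlrc5, a transactivator of class I antigen presentation genes, rose by 6.29 ± 0.32, and the interferon-inducible GTPase genes Ifi47, Gbp5 and Irgm1 rose by 5.89 ± 0.35, 5.12 ± 0.34 and 4.89 ± 0.23. Il1a rose by 6.26 ± 0.36, Mreg by 5.31 ± 0.30, Ccl4 by 5.30 ± 0.12, Cish by 5.12 ± 0.38, Schip1 by 4.85 ± 0.33 and Ralgds by 4.79 ± 0.36. The largest falls were in immunoglobulin segments, products of B lineage cells, with log2 fold changes of -6.68 ± 1.58 for Ighj2 (adjusted p = 0.0201), -5.36 ± 0.73 for Ighv1-77 and -5.0 ± 1.29 for Igkv19-93. These are short related segments whose separate values are uncertain. Summed TPM of the B and plasma cell markers was 1130.2 ± 385.9 (SD) in uninfected and 187.9 ± 49.4 in infected knockout libraries. The list itself was not called (camera adjusted p = 0.256, and adjusted p = 0.791 with an estimated correlation). Of its 14 tested members 3 were called lower and 0 higher (3 and 0 adjusted over the list alone), with a median of -0.63. In all, 1861 of 12367 genes were called, 781 higher and 1080 lower.

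Interferon-stimulated genes rose broadly in the knockout, with 40 of 47 called higher and 0 lower (43 and 0 adjusted over the list alone) and a median of 2.63 (camera adjusted p = 1.35e-38, and adjusted p = 0.00289 with an estimated correlation). Examples were Isg15, a ubiquitin-like modifier, at 2.36 ± 0.13, Ifit1, a sensor of viral RNA, at 4.25 ± 0.24, and Gbp2 at 3.14 ± 0.18. 19 of 29 NF-kB response genes rose and 0 fell (23 and 0 adjusted over the list alone). The NF-kB list had a median of 1.48 (camera adjusted p = 5.37e-20, and adjusted p = 0.124 with an estimated correlation). Sod2 rose by 3.69 ± 0.21, Icam1 by 3.39 ± 0.17, and Acod1, which encodes the enzyme that makes itaconate, by 3.30 ± 0.12. Cytokine genes rose in 10 of 19 cases and fell in 1 (10 and 1 adjusted over the list alone), among them Tnf at 3.42 ± 0.16 and Il1rn at 2.92 ± 0.19. The cytokine list had camera adjusted p = 5.92e-07, and adjusted p = 0.423 with an estimated correlation. 9 of 15 chemokine genes rose and 1 fell (9 and 2 adjusted over the list alone), with Ccl3 at 3.74 ± 0.12. The chemokine list had camera adjusted p = 2.65e-07, and adjusted p = 0.194 with an estimated correlation. Apoptosis and survival genes rose in 11 of 27 cases and fell in 1 (13 and 2 adjusted over the list alone), including Bcl2a1a at 2.49 ± 0.16, Cflar at 2.54 ± 0.20 and Bcl2l1, the gene of the survival protein Bcl-xL, at 3.14 ± 0.27. The survival list had camera adjusted p = 4.62e-06, and adjusted p = 0.184 with an estimated correlation.

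In infected knockout neutrophils granule transcripts went both ways, with more falls than rises among those called. Camp fell from 366 ± 14.7 to 38.7 ± 1.37 TPM, a log2 fold change of -3.21 ± 0.15 (adjusted p = 1.99e-06), Ltf, the lactoferrin gene, changed by -2.44 ± 0.32 and Lyz2, a lysozyme gene, by -1.81 ± 0.21, while Lcn2 rose by 2.09 ± 0.16. Of 22 secondary and tertiary granule genes, 8 fell and 3 rose (10 and 4 adjusted over the list alone). The granule list had camera adjusted p = 0.0418, and adjusted p = 0.919 with an estimated correlation. Of the 6 primary granule genes, 1 fell and 0 rose (1 and 0 adjusted over the list alone; camera adjusted p = 0.706). The camera call of the secondary and tertiary granule list was lost without the second uninfected knockout library (median -0.41, adjusted p = 0.379) and without the first or second infected knockout library (adjusted p = 0.0912 and 0.0808). Class II antigen presentation genes fell, with H2-Aa at -2.47 ± 0.27, H2-Ab1 at -2.40 ± 0.30 and H2-Eb1 at -2.47 ± 0.33, while Tap1, a peptide transporter gene of the class I pathway, rose by 3.47 ± 0.30. Over the 18 antigen presentation genes, 3 rose and 6 fell (3 and 6 adjusted over the list alone). This list had camera adjusted p = 0.595, and adjusted p = 0.966 with an estimated correlation. Dendritic cell markers, a list that shares H2-Aa, H2-Ab1 and Cd74 with it, fell in 4 of 6 cases with 0 higher (5 and 0 adjusted over the list alone). Their summed TPM went from 2104.8 ± 610.6 (SD) to 400.1 ± 44.7. This count and this sum include the shared class II genes, so they are not a separate readout of dendritic cells. The dendritic cell list had camera adjusted p = 0.00118, and adjusted p = 0.533 with an estimated correlation. Pattern recognition and phagocytic receptor genes went both ways, 8 higher and 4 lower of 30 (11 and 7 adjusted over the list alone; camera adjusted p = 0.0513), and Clec4n rose by 1.88 ± 0.14, Clec4e by 1.16 ± 0.12, Nod1, a sensor of bacterial peptidoglycan, by 1.64 ± 0.23 and the inflammasome gene Nlrp3 by 1.22 ± 0.18. The hemoglobin genes Hbb-bs and Hba-a2 changed by -1.72 ± 0.33 and -1.54 ± 0.32.

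Each of the 1861 genes called in the knockout had libraries that did not overlap between the groups. Chance alone gives this in 20% of unselected genes, and the call itself favors it. The median of all genes was -0.12, and under median-of-ratios scaling it was 0.04 and the calls were 1042 higher and 637 lower, so that the majority changed side. Quantile normalization gave 884 and 781, and removal of the length trend 884 and 754. Without the first uninfected knockout library 986 genes were called, and without the second 932, of which 523 were higher and 409 lower. Of 66 genes named for this comparison and called, 58 were called without each library in turn, and the others were Ighj2, Igkv19-93, Slc2a3, Hbb-bs, Hba-a2, Il10, Mrgpra2a and Ndrg1.

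The infection responses of wild-type and knockout neutrophils were then set side by side. Il1a changed by 6.09 ± 0.36 in wild type and 6.26 ± 0.36 in the knockout, and Ccl4 by 5.56 ± 0.12 and 5.30 ± 0.12. Of 15 chemokine genes the interaction called 4 more positive in the knockout and 0 more negative (4 and 2 adjusted over the list alone; camera adjusted p = 0.442), and of 19 cytokine genes 2 and 0 (3 and 3 adjusted over the list alone; camera adjusted p = 0.674). Cxcl9, with 3.30 ± 0.29 and 6.66 ± 0.29, and Cxcl10, with 4.19 ± 0.19 and 6.72 ± 0.19, had larger rises in the knockout, tested as the interaction. Across genes the responses of both genotypes correlated with r = 0.312 and rho = 0.191 (jackknife SE of r over libraries 0.193), and r was 0.146 without the second uninfected wild-type library. Genes are not independent replicates. In both genotypes 279 genes were called higher, where independent lists would share 25.3, and 90 were called lower, where they would share 24.6, while 12 were called in opposite directions. Both contrasts use the same estimate of the spread for each gene, which by itself raises the overlap of calls. The excess over independent lists therefore overstates how far the responses go together.

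**Figure D2:**
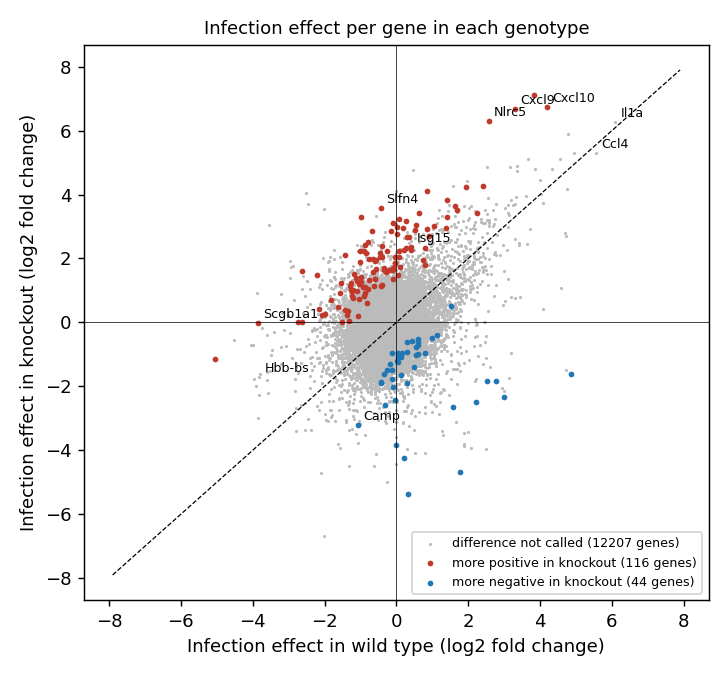
Infection effect of each of 12367 genes in wild type (horizontal) and knockout (vertical), both as log2 fold change of TPM + 1, with the dashed line marking equal effects. Red points are 116 genes with a more positive effect in the knockout and blue points 44 genes with a more negative one by the test of the difference; Cxcl9 lies at 3.30 and 6.66.

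Without infection, few transcripts were called between the genotypes. Acod1 was lower in uninfected knockout than in uninfected wild-type neutrophils, at 181 ± 11.4 against 380.1 ± 1.2 TPM (mean ± SD, n = 2 and 2), a log2 fold change of -1.07 ± 0.13 (± SE, adjusted p = 0.0364). The immunoglobulin segments Ighv2-5 and Ighv1-52 were higher in the knockout, by 4.09 ± 0.43 (adjusted p = 0.0328) and 3.60 ± 0.48 (adjusted p = 0.047), and Igkv4-86 was called higher too, listed at 0 in both uninfected wild-type libraries and at 6.69 and 25.03 TPM in the knockout ones (adjusted p = 0.047). With 2 unnamed loci that were lower, these made up the 6 genes called, 3 higher and 3 lower, where 1768 had an unadjusted p under 0.05. The 3 higher genes are all immunoglobulin segments, products of B lineage cells. Summed TPM of the B and plasma cell markers was 1130.2 ± 385.9 (SD) in uninfected knockout and 442.8 ± 236.5 in uninfected wild-type libraries. Whether B lineage cells in the sort account for these calls was not tested. Xrn1, an RNA exonuclease gene, stood at -2.40 ± 0.34 and Suco at -1.82 ± 0.26, neither past the threshold (adjusted p = 0.0644 for both). Heat shock and immediate early genes, which respond to cell handling, had a median of 0.48, with 0 of 23 called higher and 0 lower (10 and 0 adjusted over the list alone). Camera for this list gave adjusted p = 2.32e-09, and adjusted p = 0.438 with an estimated correlation. Not past the threshold over all genes were Atf3 at 1.29 ± 0.19 (adjusted p = 0.0667), Hspa8 at 1.16 ± 0.18 (adjusted p = 0.0667), Hspa1a at 2.40 ± 0.41 (adjusted p = 0.104) and Hspa1b at 2.21 ± 0.40 (adjusted p = 0.108). Alveolar macrophage markers had a median of -1.16 with 0 called higher and 0 lower of 17 (1 and 6 adjusted over the list alone), and their summed TPM was 976.5 ± 282.3 (SD) in the knockout and 2676.9 ± 1101.2 in wild type. The macrophage list had camera adjusted p = 1.61e-05, and adjusted p = 0.285 with an estimated correlation. The comparison of 2 against 2 libraries was unstable: 0 genes were called without the first uninfected wild-type library, 194 without the second, 0 without the first uninfected knockout library or without any 1 of the infected libraries except the third wild-type one, which gave 1, as well as 0 when only these groups were fitted or with a filter of 5 TPM. Without the second uninfected knockout library 0 were called higher and 4 lower, and 0 of these were among the genes called with all libraries. Libraries of the 6 called genes did not overlap, which chance gives in 33.3% of unselected genes and which the call itself favors.

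With infection, interferon-stimulated transcripts were higher in knockout than in wild-type neutrophils. Cxcl9 stood at 109 ± 6.93 TPM in infected knockout and 11.1 ± 2.77 TPM in infected wild-type neutrophils (mean ± SD, n = 3 and 3), a difference of 3.21 ± 0.26 (log2 fold change ± SE, adjusted p = 0.000474). Cxcl10 stood at 2074 ± 319.5 against 343 ± 35.6 TPM, a difference of 2.59 ± 0.17 (adjusted p = 0.000265), and Isg15 at 1573 ± 89.5 against 474 ± 21.1 TPM, a difference of 1.73 ± 0.11 (adjusted p = 0.000265). Interferon-induced and antiviral genes were among the largest differences, a description that was not tested beyond the interferon-stimulated list. Ifih1, a sensor of double-stranded RNA, differed by 2.20 ± 0.32, Ddx60 by 2.07 ± 0.28 and Slfn4 by 2.30 ± 0.32. Rnf213 differed by 2.29 ± 0.29, Herc6, a ligase for Isg15 in mice, by 2.13 ± 0.30 and Trafd1 by 2.12 ± 0.16. Ccdc167 was higher by 2.43 ± 0.43, Calhm6 by 2.39 ± 0.35, Daxx, a histone chaperone gene, by 2.36 ± 0.21 and Nlrc5 by 2.11 ± 0.29. Camp was lower in the knockout, at 38.7 ± 1.37 against 136 ± 12.7 TPM, a log2 fold change of -1.78 ± 0.13 (adjusted p = 0.000474). Further genes lower in the knockout were the immunoglobulin segment Iglc3 at -1.68 ± 0.30, Bub3 at -1.38 ± 0.24, Rgs19, a regulator of G protein signaling, at -1.09 ± 0.20, Zdhhc18 at -1.08 ± 0.18, Hnrnpu at -0.93 ± 0.17, Tsc22d3, a glucocorticoid-induced gene, at -0.88 ± 0.14, Cstb at -0.68 ± 0.12 and Atp6v0e at -0.62 ± 0.11.

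Of 47 interferon-stimulated genes, 24 were higher and 0 lower in infected knockout neutrophils (41 and 0 adjusted over the list alone), with a median of 1.33 (camera adjusted p = 7.26e-46, and adjusted p = 0.00289 with an estimated correlation). Gbp2 was higher by 1.52 ± 0.16 and Irgm1 by 1.67 ± 0.20. Their summed TPM was 7667 ± 490.5 (SD) in infected knockout and 2858.5 ± 99.8 in infected wild-type libraries, against 1509 ± 128.1 and 1597.4 ± 244.4 without infection. Without infection 0 interferon-stimulated genes were called higher and 0 lower in the knockout (0 and 0 adjusted over the list alone), with a median of -0.11 (camera adjusted p = 0.732). Antigen presentation genes were higher in 2 of 18 cases and lower in 0 (4 and 0 adjusted over the list alone), namely Tap1 at 1.78 ± 0.27 and the immunoproteasome gene Psmb9 at 0.93 ± 0.16. That list had camera adjusted p = 0.0069, adjusted p = 0.0641 without the third infected knockout library, and adjusted p = 0.778 with an estimated correlation. Without infection the antigen presentation list was also higher in the knockout, with a median of 0.53 against 0.20 with infection and 0 genes called higher and 0 lower (0 and 0 adjusted over the list alone). There camera gave adjusted p = 0.000347, and adjusted p = 0.633 with an estimated correlation, and the call was lost without the first uninfected wild-type or the second uninfected knockout library (adjusted p = 0.15 and 0.131). Dendritic cell markers, a list that shares class II genes with it, summed to 2104.8 ± 610.6 TPM (SD) in uninfected knockout libraries. In uninfected wild-type libraries the sum was 1117.7 ± 665.5. Whether other cells in the sort account for this difference of the antigen presentation list is left open. With infection, 1 of 29 genes in the NF-kB list was higher, Acod1 at 0.82 ± 0.11, and 0 lower (4 and 0 adjusted over the list alone). Its camera adjusted p was 0.0239, and adjusted p = 0.778 with an estimated correlation. This call was lost without the first or the third infected wild-type library (adjusted p = 0.054 and 0.0529) and without the first or the third infected knockout library (adjusted p = 0.0937 and 0.106). Hk2, a hexokinase gene of glycolysis, was higher by 1.50 ± 0.25 and Casp4, which encodes caspase 11, the sensor of cytosolic lipopolysaccharide in mice, by 1.16 ± 0.22. Scgb1a1 was also higher in the infected knockout, at 408 ± 105 against 105 ± 15.8 TPM, a difference of 1.93 ± 0.36 (adjusted p = 0.0466). The epithelial markers had a median of 0.84, with 1 of 13 higher and 0 lower (2 and 0 adjusted over the list alone). The epithelial list had camera adjusted p = 0.0087, and adjusted p = 0.387 with an estimated correlation.

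In total 99 genes were called between the genotypes with infection, 85 higher and 14 lower in the knockout. None had overlapping libraries, which chance gives in 10% of unselected genes and which the call itself favors. The count was 25, 40 and 22 without the first, the second and the third infected wild-type library, and 28 and 38 without the first and second infected knockout library. The excess of higher calls was smaller without the third infected knockout library, with 63 higher and 41 lower, 59 of the 99 among them, and with sample weights, with 114 higher and 42 lower. Of 30 genes named for this comparison and called, Cxcl9, Cxcl10, Daxx, Trafd1, Camp, Isg15, Gbp2 and Irgm1, 8 in all, were called without each library in turn.

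**Figure D3:**
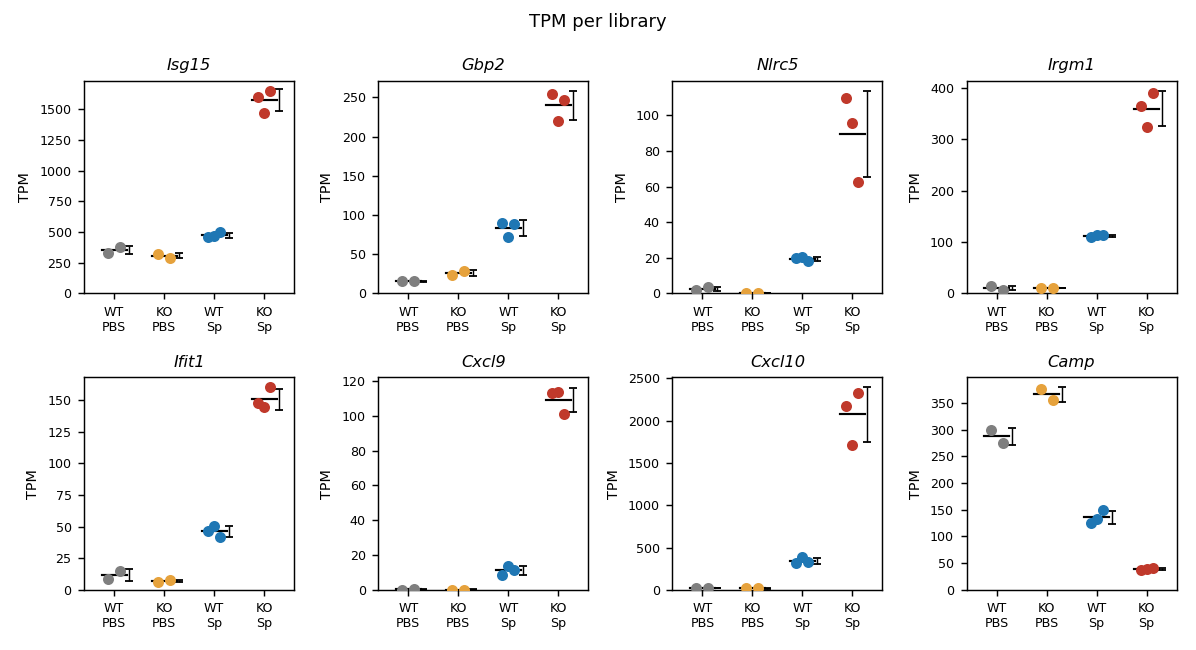
TPM of 8 genes in each library, with points for libraries, horizontal lines for group means and vertical bars for SD (WT, wild type; KO, knockout; Sp, S. pneumoniae; 2 uninfected and 3 infected libraries per genotype). In infected knockout libraries Isg15 stands at 1573 ± 89.5 and Cxcl10 at 2074 ± 319.5 TPM, above infected wild type, and Camp stands lower at 38.7 ± 1.37 TPM.

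The interaction tests, gene by gene, whether the infection response itself differed between the genotypes. Slfn4, a myeloid Schlafen gene, had a response larger by 4.0 ± 0.51 in the knockout (log2 ± SE, adjusted p = 0.00955), Nlrc5 by 3.72 ± 0.45 (adjusted p = 0.00942) and Cxcl9 by 3.36 ± 0.41 (adjusted p = 0.00942). Cxcl10 differed by 2.54 ± 0.27, Isg15 by 1.95 ± 0.18 and Acod1, which was lower without and higher with infection in the knockout, by 1.89 ± 0.17. Camp differed the other way, by -2.13 ± 0.21 (adjusted p = 0.00511), a larger fall in the knockout. More positive responses were also found for Scgb1a1 at 3.82 ± 0.57, Ccdc167 at 3.68 ± 0.68, Ddx60 at 3.53 ± 0.44, Parp10 at 3.32 ± 0.42, the ubiquitin ligase gene Huwe1 at 3.30 ± 0.61, Xrn1 at 3.27 ± 0.43, Rnf213 at 3.25 ± 0.45, the lysosomal cholesterol transporter gene Npc1 at 3.19 ± 0.54 and Atp11a at 3.14 ± 0.36. More negative ones were found for Ap3m1 at -2.41 ± 0.43, Hfe, a regulator of iron uptake, at -2.25 ± 0.45, Rgs19 at -1.86 ± 0.31, the stress-induced transcription factor gene Atf3 at -1.76 ± 0.25, Tprgl at -1.75 ± 0.33 and the mitochondrial ADP/ATP carrier gene Slc25a5 at -1.65 ± 0.28. 9 of 47 interferon-stimulated genes had a more positive response and 0 a more negative one (36 and 0 adjusted over the list alone), with a median of 1.47 (camera adjusted p = 5.37e-20, and adjusted p = 0.0116 with an estimated correlation). Among them were Ifit1 at 2.31 ± 0.35 and Oas3, an antiviral oligoadenylate synthetase gene, at 2.46 ± 0.40. Inflammatory genes with a more positive response were Tnf at 1.18 ± 0.23, Tnfaip2 at 2.72 ± 0.49, Cxcl2, a neutrophil chemoattractant gene, at 1.01 ± 0.19, Ccl5 at 2.92 ± 0.58 and Il18 at 2.07 ± 0.41, a cytokine gene that the alveolar macrophage list also holds. An interaction can rest on a difference between the uninfected groups as well as on one between the infected groups. Without infection, Xrn1 and Scgb1a1 stood lower and Atf3 higher in the knockout, each not past the threshold. Of the genes called for the interaction, 53 were also called between the genotypes with infection and 6 without it. Altogether 160 genes were called, 116 more positive and 44 more negative in the knockout. This count was 24 without the first uninfected wild-type library, 679 without the second, 71 and 50 without the first and second uninfected knockout library, 31, 29 and 32 without each infected wild-type library, and 34 and 26 without the first and second infected knockout library. The majority changed side without the second uninfected wild-type library, with 309 more positive and 370 more negative, and was narrower without the third infected knockout library, with 84 and 58, with the length trend removed, with 91 and 76, and with the filter of 5 TPM, with 211 and 128. Of 34 genes named for the interaction and called, Nlrc5, Cxcl9, Atp11a, Camp, Isg15, Cxcl10 and Acod1, 7 in all, were called without each library in turn, and 25 lost the call without the first uninfected wild-type library.

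Averages over the other factor use all 10 libraries at once. Infection averaged over genotypes gave 2001 genes, 793 higher and 1208 lower, against 982 and 687 with median-of-ratios scaling 939 and 793 with quantile normalization and 996 and 735 with the length trend removed, and 1031 of them had a log2 fold change of at least 1 in size. Genotype averaged over infection gave 8 genes, all higher in the knockout, among them the interferon-induced Cxcl10 at 1.32 ± 0.13, Gbp2 at 1.13 ± 0.13, Plac8 at 1.01 ± 0.12, Gbp2b at 0.90 ± 0.11, the proteasome activator gene Psme2 at 0.80 ± 0.09 and Isg15 at 0.75 ± 0.09 (adjusted p = 0.0216). Each of these 6 named genes lost the call without at least 1 library. In the averaged comparison 0 genes were called without the first uninfected wild-type, the first uninfected knockout, any infected wild-type, or the first or the third infected knockout library. The count was 24, 5 (2 higher and 3 lower) and 1 without the second uninfected wild-type, second uninfected knockout and second infected knockout library.

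The lists of N1-type and N2-type genes, fixed from general knowledge and not from these samples, address the question in the title. N1-type genes rose with infection in both genotypes. In wild type 7 of 12 rose and 0 fell (8 and 0 adjusted over the list alone; camera adjusted p = 4.57e-14, and adjusted p = 0.077 with an estimated correlation). In the knockout 8 rose and 0 fell (8 and 0 adjusted over the list alone; camera adjusted p = 2.74e-10, and adjusted p = 0.0997 with an estimated correlation). In wild type these were Ccl3, Cxcl10, Icam1, Cxcl9 at 3.30 ± 0.29, Tnf at 2.23 ± 0.16, Il12a, a subunit gene of interleukin 12, at 1.70 ± 0.23 and the death receptor gene Fas at 1.26 ± 0.15. In the knockout the same 7 genes rose, with Il12a at 3.14 ± 0.23 and Fas at 1.21 ± 0.15, and Nos2, the inducible nitric oxide synthase gene, rose by 2.25 ± 0.36. Between infected knockout and infected wild type, 2 N1-type genes were higher, Cxcl9 and Cxcl10, and 0 lower (6 and 0 adjusted over the list alone), while Il12a at 1.03 ± 0.20 and Nos2 at 1.43 ± 0.32 were not past the threshold over all genes (adjusted p = 0.0594 and 0.0964). For this difference of the N1-type list camera gave adjusted p = 1.81e-05, and adjusted p = 0.272 with an estimated correlation. The interaction called 3 N1-type genes, Cxcl10, Cxcl9 and Tnf, all more positive in the knockout (5 and 0 adjusted over the list alone), with camera adjusted p = 0.0172, and adjusted p = 0.6 with an estimated correlation. That camera call was lost without the second uninfected wild-type library (adjusted p = 0.0591) and without the third infected knockout library (adjusted p = 0.0771). Without infection 0 N1-type genes were called higher and 0 lower (0 and 1 adjusted over the list alone; camera adjusted p = 0.91).

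N2-type genes did not move together. In wild type 2 of 12 rose and 1 fell with infection (3 and 5 adjusted over the list alone; camera adjusted p = 0.92). Tgfb1, the gene of transforming growth factor beta, rose by 2.28 ± 0.38, Retnla fell, and Arg1, the arginase gene, was called higher, listed at 0 in both uninfected libraries and at 1.71, 2.28 and 2.80 TPM in the infected ones. In the knockout 2 rose and 1 fell (2 and 1 adjusted over the list alone; camera adjusted p = 0.92). The chemokine gene Ccl5 changed by 3.17 ± 0.41, the anti-inflammatory cytokine gene Il10 by 1.74 ± 0.50 (adjusted p = 0.0437) and Retnla by -2.13 ± 0.36. Between infected genotypes 0 were called higher and 0 lower (2 and 1 adjusted over the list alone; camera adjusted p = 0.997), with Arg1 at -1.38 ± 0.27 in the knockout (adjusted p = 0.057). Without infection the counts were 0 and 0 (0 and 2 adjusted over the list alone; camera adjusted p = 0.908). The interaction called 1 higher, Ccl5, and 0 lower (1 and 2 adjusted over the list alone; camera adjusted p = 0.92). Not past the threshold were Arg1 (adjusted p = 0.121), for which no fold change is given, and Tgfb1 at -1.71 ± 0.53 (adjusted p = 0.125). The N2-type list shares Mrc1 and Chil3 with the alveolar macrophage markers. Of these 17 markers 0 were called higher and 1 lower (1 and 9 adjusted over the list alone) with infection in wild type, with camera adjusted p = 0.0206, and adjusted p = 0.622 with an estimated correlation; the camera call was lost without the second uninfected wild-type library (adjusted p = 0.151). Whether macrophages in the sort account for N2-type values is left open.

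**Figure D4:**
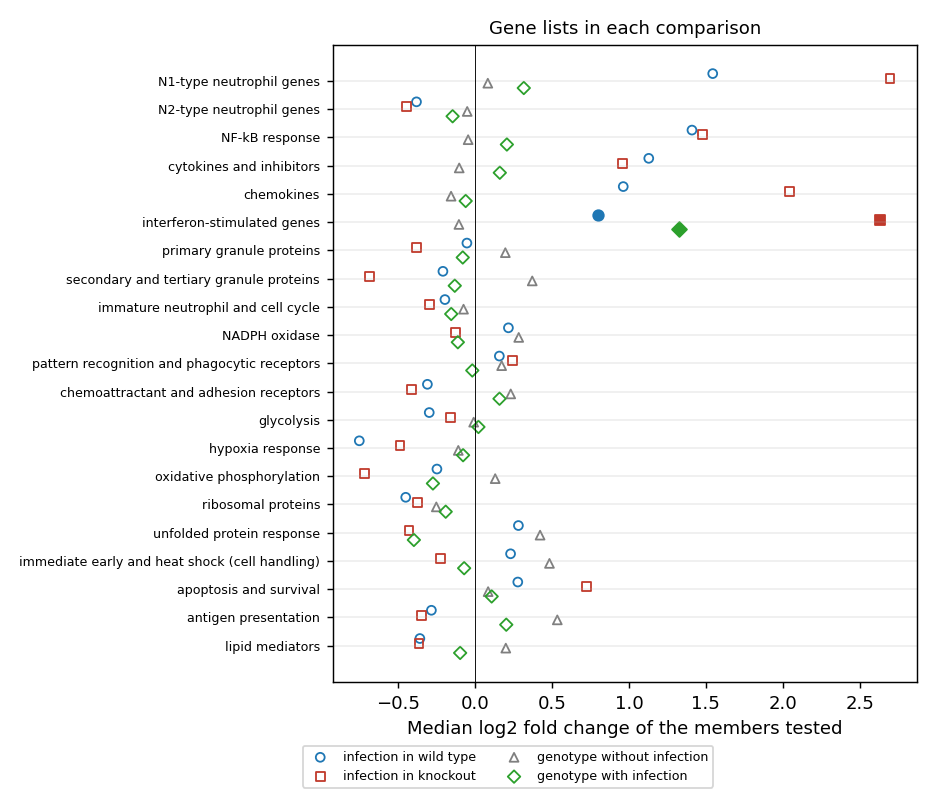
Median log2 fold change of the tested members of each list of neutrophil states and functions in 4 comparisons, where filled markers have an adjusted p under 0.05 with an estimated correlation and open markers do not. Interferon-stimulated genes have the only filled markers, at 0.80 for infection in wild type, 2.63 for infection in the knockout and 1.33 for genotype with infection.

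Markers of other cell types were present in the sorted libraries and moved with the groups. Erythroid markers fell with infection in wild type, 4 of 6 lower and 0 higher (5 and 1 adjusted over the list alone; camera adjusted p = 2.93e-05, and adjusted p = 0.359 with an estimated correlation). In the knockout 4 fell and 0 rose (4 and 0 adjusted over the list alone; camera adjusted p = 0.0484, and adjusted p = 0.721 with an estimated correlation). The camera call in the knockout was lost without either uninfected wild-type library (adjusted p = 0.0921 and 0.0866), the first uninfected knockout (0.224), the first infected wild-type (0.0514) and the first or the third infected knockout library (0.0517 and 0.0975). Their summed TPM in uninfected knockout libraries, 2814.9 ± 1090.5 (SD), lay below that in uninfected wild type, with 0 members called higher and 0 lower (0 and 4 adjusted over the list alone; camera adjusted p = 0.000624, and adjusted p = 0.504 with an estimated correlation). Epithelial markers fell in wild type with infection, 5 of 13 lower and 1 higher (6 and 1 adjusted over the list alone; camera adjusted p = 0.00385, and adjusted p = 0.312 with an estimated correlation), and their summed TPM was 691.7 ± 331 in uninfected and 564.2 ± 90.4 in infected knockout libraries. Neutrophil identity transcripts such as those of the calprotectin subunits made up a summed TPM of 148126 ± 7550 and 113643 ± 2692 in uninfected wild-type and knockout libraries and 115007 ± 7387 and 131902 ± 18598 in infected ones. Nothing in the labels used here says how pure the sorted cells were.

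**Figure D5:**
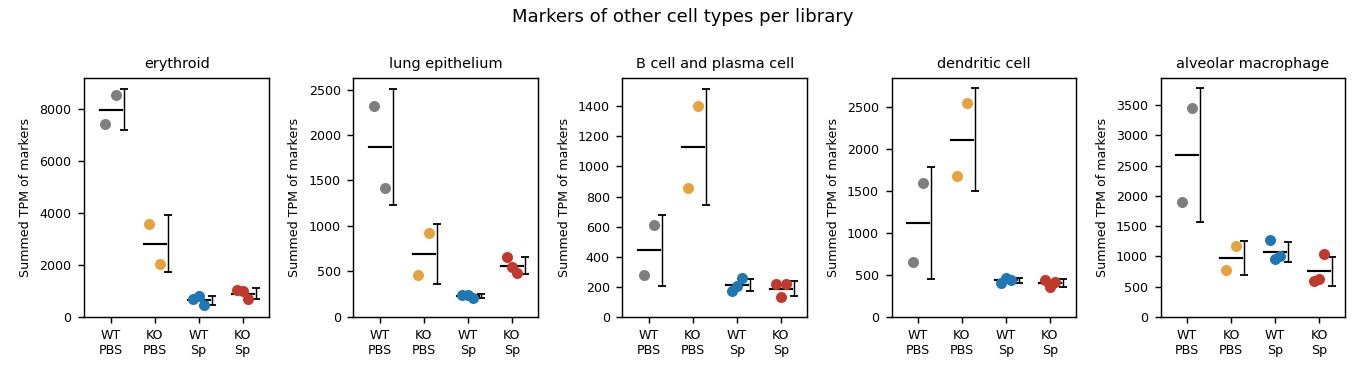
Summed TPM of the markers of 5 other cell types in each library, with points for libraries, horizontal lines for group means and vertical bars for SD (WT, wild type; KO, knockout; Sp, S. pneumoniae). Erythroid markers average 7970.4 TPM in uninfected wild-type and 632 TPM in infected wild-type libraries. The sum of the B and plasma cell markers, which a few abundant members can carry, is highest in uninfected knockout libraries at 1130.2 TPM.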

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

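The tests of RNA from other immune cells, of RNA from lung epithelium and of exchanged genotype labels were chosen only after the result was seen, as was the removal of the length trend as a setting; the other tests were planned.

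Interferon-stimulated genes responded more strongly to infection in the knockout, with a median difference of 1.47 (log2) between the infection effects and 24 of 47 members called higher in infected knockout than in infected wild-type neutrophils. A trend of the libraries on transcript length is argued against, since its removal moved the median difference with infection from 1.33 to 1.41 (1.38 to 1.45 with each library left out) and the members called from 24 to 25. A larger share of RNA from other immune cells, as the source of the whole difference, is argued against for the 8 types tested. The highest median difference among their markers, that of T cells, was 0.358. In each type it lay below that of the interferon-stimulated genes by more than the SD over markers. A stronger interferon response within such cells at an unchanged share would leave their markers flat, so this test cannot exclude it. RNA from lung epithelium cannot be told apart, with a median difference of 0.842 over markers that spread by an SD of 0.88, and interferon-induced transcripts in neutrophils themselves could equally give this pattern. Of the 10 splits of the 6 infected libraries, 1, the real one, called 99 genes and the highest other called 1, and 10 splits are too few for a share under 0.05.

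Across genes, the genotype effects without and with infection ran in opposite directions, with r = -0.217 and rho = -0.266, and the groups compared share no library. A trend on transcript length is argued against, since r was -0.198 once it was removed (-0.214 to -0.114 with each library left out). An effect of 1 library as the only source is argued against, since r stayed at -0.129 or further from 0 with each left out. The jackknife SE of r over libraries was 0.097. Of 30 splits of the libraries within infection state, 1, the real one, gave an r as far from 0, with 0.194 as the highest of the others. That is the smallest share 30 splits can give, and it lies under 0.05 by a narrow margin. The -0.129 found without the first uninfected wild-type library is closer to 0 than several of the other splits of all libraries. Chance is therefore not firmly excluded. Differences between the mice or the sorts behind the uninfected libraries, which the labels do not describe, stay open and were not tested, beside an effect of the genotype that depends on infection. Summed TPM of the lung epithelial markers also changed side, at 691.7 in knockout against 1866.3 in wild type without infection and 564.2 against 227.3 with it. That of the alveolar macrophage markers did not, at 976.5 against 2676.9 and 749 against 1071.8. Among the other cell types both patterns occurred. Whether the share of other cells gives the negative r was not tested.

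Mrgpra1 was listed at 0 in each wild-type library. Reads assigned to near-identical family members are argued against, because 85.7% of the 1058 words of 31 bases in its transcript occur in no other gene, while 151 are shared. Exchanged genotype labels cannot be told apart from correct ones by this gene, since its highest value in any library was 0.0209 TPM, in the second uninfected knockout library. A level below what these libraries detect stays open, since the depth is unknown, and no biological explanation was tested.

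The other results here are genes whose infection effect differed between the genotypes by the interaction test, given as the effect in the knockout minus that in wild type (log2). Part of such a difference can lie between the uninfected groups. Among interferon-induced and antiviral genes the difference was 4.0 for Slfn4, 3.72 for Nlrc5, 3.53 for Ddx60, 3.36 for Cxcl9, 3.32 for Parp10 and 3.25 for Rnf213. It was 2.79 for Daxx, 2.73 for Trafd1, 2.54 for Cxcl10, 2.46 for Oas3, 2.31 for Ifit1, 1.95 for Isg15 and 1.83 for Gbp2b. Among cytokine and inflammatory genes it was 2.92 for Ccl5, 2.72 for Tnfaip2, 2.07 for Il18, 1.89 for Acod1, 1.18 for Tnf and 1.01 for Cxcl2. Further positive differences were 3.82 for Scgb1a1, 3.68 for Ccdc167, 3.30 for Huwe1, 3.27 for Xrn1, 3.19 for Npc1, 3.14 for Atp11a, 2.25 for Suco, 2.18 for Hk2 and 1.22 for Vav1. Negative differences were -0.91 for Atp6v0e, -1.13 for Dnaja1, -1.27 for Hspa8, -1.28 for Sdhd, -1.51 for Zdhhc18, -1.60 for Tsc22d3 and -1.65 for Slc25a5. Larger ones were -1.75 for Tprgl, -1.76 for Atf3, -1.86 for Rgs19, -2.13 for Camp, -2.25 for Hfe and -2.41 for Ap3m1. The immunoglobulin segments Ighv1-52 and Ighv1-77, whose separate values are uncertain, differed by -4.24 and -5.69. Ighv2-5, listed at 0 in the infected knockout libraries, and Igkv4-86, listed at 0 in all but the uninfected knockout libraries, were called too (adjusted p = 0.00955 and 0.0313), and no fold change is given for them.

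Several lists were called by camera for the same difference, and except for the interferon-stimulated genes none of these calls held with an estimated correlation. The median difference was 0.41 for N1-type genes (adjusted p = 0.6 with an estimated correlation), -0.45 for secondary and tertiary granule genes (adjusted p = 0.907), -0.43 for oxidative phosphorylation (adjusted p = 0.285) and -0.82 for the unfolded protein response (adjusted p = 0.6). For heat shock and immediate early genes it was -0.63 (adjusted p = 0.6 with an estimated correlation) and for neutrophil identity 0.48 (adjusted p = 0.778). Markers of alveolar macrophages differed by 0.56 (adjusted p = 0.622), of T cells by 1.01 (adjusted p = 0.56), of lung epithelium by 0.90 (adjusted p = 0.435) and of erythroid cells by 1.97 (adjusted p = 0.56), each with an estimated correlation. The camera call of the granule list was lost in 6 of 10 cases of 1 library left out, and its median difference was -0.09 without the first uninfected wild-type library (adjusted p = 0.4) and -0.11 without the second uninfected knockout library (adjusted p = 0.393). It was also lost without the first or second infected wild-type library (0.0627 and 0.0506) and without the first or second infected knockout library (0.104 and 0.0742). Without the second uninfected wild-type library the calls of N1-type genes, neutrophil identity, alveolar macrophages and T cells were lost (adjusted p = 0.0591, 0.248, 0.151 and 0.219, with a T cell median of 0.64). Without the third infected knockout library those of N1-type genes, neutrophil identity and alveolar macrophages were lost (adjusted p = 0.0771, 0.0533 and 0.08), and that of neutrophil identity also without the first uninfected knockout library (adjusted p = 0.0733).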

How the results depend on the processing

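The removal of the length trend was chosen after the data were seen; all other settings were planned. Depth is unknown, and a group left with 1 library is assumed to vary like the others. Changes of sign among results called in neither fit count as unchanged. The cause was not tested except where a setting tests fewer genes or libraries. Of 215 named genes in their contrasts 196 were called, and 135 to 195 with each library left out and 149 to 194 under the other settings. With each library left out, 1689 gene results kept direction and side of the threshold, 452 fell below it and 7 rose past it; over the 83 list calls, 751 results kept both, 77 lost the call and 2 reversed. Among the other settings, most gene calls, 48, were lost without a filter and without the variance trend, and most list calls, 12, with the filter of 5 TPM.

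Genotype without infection, with 6 genes, gave 0 with a pseudocount of 0.1, with the filter of 5 TPM, with sample weights or with only its 2 groups, 28 without a filter and 3 without the variance trend, and 0 to 194 with each library left out. Genotype with infection, with 99, gave 48 without a filter, 56 without the trend and 156 with weights, and 22 to 106 with each library left out. The interaction, with 160, gave 84, 35 and 81 in that order, 339 with the filter of 5 TPM, and 24 to 679 with each left out. Infection in wild type, with 682, gave 393 with only its 2 groups and 298 to 654; infection in the knockout, with 1861, gave 932 to 2014. Infection averaged over genotypes, with 2001, gave 1031 at a log2 fold change of at least 1 in size and 1404 to 1858. Genotype averaged over infection, with 8, gave 18 with a pseudocount of 5, 21 without a filter, 14 with the filter of 5 TPM, 14 and 15 with median-of-ratios and quantile scaling, 0 without the trend, 17 with the length trend removed, 5 at a log2 fold change of at least 1 in size and 0 to 24. For the ribosomal proteins list, genotype without infection, the median of -0.253 ranged from -0.438 to -0.061 with each library left out, and the camera direction reversed without the first uninfected wild-type (-0.061, adjusted p = 0.954) and without the second uninfected knockout library (-0.064, adjusted p = 0.941). The correlation of infection effects, 0.312, was 0.146 to 0.424 with each library left out and 0.245 to 0.382 otherwise, and that of genotype effects, -0.217, was -0.232 to -0.129 and -0.295 to -0.134.

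With the replicate number as a replicate block, the counts were 440 for infection in wild type, 0 for genotype without infection, 53 for genotype with infection, 73 for the interaction and 0 for genotype averaged over infection; the other counts were within 1.5 times, and 47 named genes and 3 lists lost the call. Deviations of same-numbered libraries correlated at 0.185 without infection and -0.013, 0.015 and -0.006 with infection, and not each library correlated best with its own number. With 2 libraries per uninfected group, the differently numbered pairs mirror this value at -0.185. Mitochondrial transcripts took 1.84% and 1.51% of the TPM in the first uninfected wild-type and knockout libraries. In the second ones they took 0.82% and 0.43%. The numbers do not pair the infected libraries, and whether they pair the uninfected ones is left open.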

Other observations

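The test of the N1-type list without its interferon-induced chemokines was planned.

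Genes of mitochondrial respiration fell in infected knockout neutrophils. Of 38 oxidative phosphorylation genes 17 fell and 0 rose (28 and 0 adjusted over the list alone), with a median of -0.72 (camera adjusted p = 2.68e-09, and adjusted p = 0.124 with an estimated correlation). The ATP synthase genes Atp5c1 and Atp5a1 changed by -1.49 ± 0.20 and -1.35 ± 0.22 (log2 fold change ± SE), Sdhd, a subunit gene of succinate dehydrogenase, by -1.23 ± 0.18 and Ndufa6, of complex I, by -1.01 ± 0.17. In wild type 2 fell and 0 rose (4 and 0 adjusted over the list alone). Camera there gave adjusted p = 0.0445, and adjusted p = 0.633 with an estimated correlation. Summed TPM of these genes was 10519.3 and 9261 in the first and second uninfected knockout library, against 9046.5 and 8772.1 in the wild-type ones. With infection it was 6526.1 ± 486.2 (SD) in the knockout and 7749.1 ± 218 in wild type. Part of the larger fall in the knockout thus lay in its uninfected libraries, mainly the first. The difference of the infection effects was called for Sdhd alone among these genes, at -1.28 ± 0.25 (adjusted p = 0.0481), and that call was lost in 9 of 10 cases of 1 library left out (highest adjusted p = 0.156, without the first uninfected wild-type library). Ribosomal protein genes fell in 11 of 50 cases and rose in 0 in the knockout (16 and 0 adjusted over the list alone; camera adjusted p = 6.7e-05, and adjusted p = 0.778 with an estimated correlation). That camera call was lost without the first uninfected knockout library (adjusted p = 0.0946), and the one in wild type for oxidative phosphorylation in 6 cases, among them the second infected wild-type library (adjusted p = 0.119). In wild type the ribosomal protein list was lower too, with a median of -0.45 against -0.37 in the knockout and 2 genes that fell and 0 that rose (0 and 0 adjusted over the list alone; camera adjusted p = 7.18e-07, and adjusted p = 0.633 with an estimated correlation). The interaction had camera adjusted p = 0.92 for this list. Ribosomal protein genes took 3.30% and 2.94% of the TPM in the first uninfected wild-type and knockout libraries and 2.54% and 2.33% in the second. In infected libraries they took 1.82% to 2.21%. With a median of all genes that moves by over 0.1 under median-of-ratios scaling in the knockout, these falls are relative to the scaling used.

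Called genes of glycolysis and of the response to low oxygen went both ways. Pfkfb3, which makes an activator of glycolysis, rose by 2.06 ± 0.32 in wild type and 2.54 ± 0.32 in the knockout, and Egln3, an oxygen-sensing hydroxylase gene, by 2.41 ± 0.31 and 2.18 ± 0.31. In the knockout Hk2 rose by 2.25 ± 0.28, with a difference between the genotypes of 2.18 ± 0.40 (adjusted p = 0.0381), while the glucose transporter gene Slc2a3 changed by -1.70 ± 0.32, Ldha by -1.15 ± 0.19, Bnip3 by -1.65 ± 0.30, Mxi1 by -1.62 ± 0.29 and Ndrg1 by -1.54 ± 0.32. The lactate exporter gene Slc16a3 changed by -1.56 ± 0.35 in wild type. The calls of Slc2a3 and Ndrg1 were lost without the second uninfected knockout library (adjusted p = 0.0577 and 0.0922), that of Slc16a3 without 4 of the libraries (highest adjusted p = 0.13, without the second uninfected wild-type library), and that of the Hk2 difference without 9 (highest adjusted p = 0.135, without the first uninfected wild-type library). Of 19 glycolysis genes 3 rose and 5 fell in the knockout (3 and 5 adjusted over the list alone; camera adjusted p = 0.706), and of 17 hypoxia response genes 1 rose and 6 fell (2 and 6 adjusted over the list alone; camera adjusted p = 0.393). In wild type 1 glycolysis gene rose and 2 fell (1 and 2 adjusted over the list alone; camera adjusted p = 0.393). The hypoxia response list was lower there as a whole, with a median of -0.75, 1 higher and 1 lower (2 and 7 adjusted over the list alone). This had camera adjusted p = 0.0279, adjusted p = 0.151 without the second uninfected wild-type library, and adjusted p = 0.438 with an estimated correlation.

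Some heat shock genes, which also respond to cell handling, fell with infection in the knockout, with Hspa1b at -3.38 ± 0.37, Hspa1a at -3.05 ± 0.38, Hspa8 at -1.60 ± 0.16 and Dnaja1 at -1.31 ± 0.13. Over the list of 23 heat shock and immediate early genes 2 rose and 9 fell (5 and 9 adjusted over the list alone; camera adjusted p = 0.175). In wild type 6 rose and 1 fell (8 and 2 adjusted over the list alone), with camera adjusted p = 0.00595, adjusted p = 0.111 without the first uninfected wild-type library, and adjusted p = 0.778 with an estimated correlation. The difference of the infection effects was -1.27 ± 0.23 for Hspa8 (adjusted p = 0.0382) and -1.13 ± 0.19 for Dnaja1 (adjusted p = 0.0313). Cd74, the class II invariant chain gene, changed by -2.37 ± 0.38 in the knockout, and Vav1, an exchange factor gene of immune cell signaling, differed between the infection effects by 1.22 ± 0.25 (adjusted p = 0.0491). These interaction calls were lost in 8 cases of 1 library left out for Hspa8 and Dnaja1 and in 9 for Vav1, with the highest adjusted p, 0.135, 0.12 and 0.167, without the first uninfected wild-type library. Csf3 was called higher in infected knockout neutrophils too, listed at 0 in both uninfected libraries and at 17.77, 16.48 and 17.4 TPM in the infected ones. Without infection, Car4 at -1.59 ± 0.33 (adjusted p = 0.141), Il18 at -1.34 ± 0.32 (adjusted p = 0.17) and Scgb1a1 at -1.90 ± 0.44 (adjusted p = 0.167) were not past the threshold between the genotypes.

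The hypothesis that the interferon-induced Cxcl9 and Cxcl10 alone carry the difference of the N1-type list between infected genotypes was not borne out. Camera gave an unadjusted p of 2.51e-06 for all 12 genes, with a median of 0.32, and 0.00619 for the 10 that remain without this pair, with a median of 0.23. The list as a whole was not called with an estimated correlation, so the difference of the remaining genes may rest on the preset correlation.

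Of all 100 splits of the libraries within genotype, 1, the real one, called as many as the 2001 genes of infection averaged over genotypes. The highest other called 138. That is the smallest share 100 splits can give, and it lies under 0.05, so chance is argued against. For genotype averaged over infection, 3 of 60 splits, the real one included, called at least the 8 genes of the real split. The highest other called 160, a structure of the samples that is the interaction itself, since that split exchanges the genotype labels of the infected libraries. The remaining split called 13 and kept the real genotype labels of the infected libraries. Both hold real structure, so these splits cannot decide the question, and chance is not excluded.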
